A study of Drosophila melanogaster with 3 samples.

How the data were processed

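The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) for the transcription factor Deaf1 in Drosophila melanogaster. Per the labels, the material was whole embryos of mixed sex, aged 0 to 24 hours, from a fly line that stably carries Deaf1 with green fluorescent protein (GFP) at its C terminus, and chromatin was recovered with an antibody against GFP. The labels number 3 biological replicates of this 1 group, and they name no other condition. The labels name 1 possible control experiment, which was not used here.

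The authors deposited peak lists on the dm6 build, per the labels. Per the file headers, peaks were called on each replicate's alignment and on the pooled alignments, each time against 1 control alignment, and an optimal set was then derived from these lists with the irreproducible discovery rate (IDR), a measure of rank agreement between replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list hold 30000 peaks, a fixed length, so weak peaks at the bottom of a list are relaxed calls that include background. The IDR set holds 8667 summits in 7673 intervals, since 875 intervals hold more than 1 summit. Each of these 8667 summits is also in the pooled list, and they are its 8667 peaks of highest signal: the lowest IDR signal was 256.1 and the highest signal outside the set was 256.055.

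The deposited peak signal is the caller's own value per peak, not scaled between lists, and was used here only to rank and describe peaks within a list. The deposited −log10 q-values reach a ceiling of 4.386 in the pooled list, shared by 12172 of its peaks and by each IDR peak, so they separate no IDR peak from another and were not used to rank. Read counts were not used here and the sequencing depth is unknown, so no interval below covers the counting error of reads. Intervals printed with shares are 95% exact Clopper-Pearson intervals over peaks or genes, and neighbouring peaks and genes are not independent. Where a value could be taken per replicate, it is given as mean ± SD over the 3 replicates, either from the top 8667 peaks of each replicate list or as the replicate's signal divided by the median signal of its own list. For named genes and for the correlation of word number with signal, the replicate's signal is that of its nearest summit among its peaks that hold the IDR summit. For the correlation between replicates it is the highest signal of those peaks, which differed from the nearest at 834 to 879 summits per replicate.

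Coordinates are 1-based on dm6. Sequence came from the RefSeq copy of the fly genome and genes from Ensembl release 115, both on the same assembly. Peaks lay on 6 arms (2L, 2R, 3L, 3R, 4 and X). A promoter peak has its summit within 500 bp of any of the 19607 annotated transcription start sites (TSSs) of 13945 protein-coding genes, a distal peak lies over 2000 bp from each of them, and a gene is called bound when an IDR summit lies within 500 bp of 1 of its TSSs. Each summit was also assigned to 1 annotation class, with promoter first and then coding exon, 5′ UTR, 3′ UTR, non-coding exon, intron and intergenic in order of priority; placements for these classes were drawn 1000 times and those for distances to a TSS 100 times.

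The tests in this paragraph and the gene lists were fixed before the data were examined. The annotation classes, the position relative to the TSS, the anagrams of TTCGG, the word profiles, the correlation of word number with signal and the random gene sets matched on TSS number were added later, and other late comparisons carry a remark where they are given. The promoter share was compared with 1000 random placements of the summits on their own arm (one-sided permutation test). Sequence words were sought on both strands in the 101 bp around each summit and in an equal window centred 300 bp to the right, with an exact two-sided McNemar test, for 11 listed words and for 2080 6-mers with Benjamini-Hochberg adjustment. Bound shares of 20 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the lists; the same test compared genes of divergent promoters with other genes, and genes of the X with those of 2L, 2R, 3L and 3R. Promoter and distal signals were compared with a permutation test of the difference in medians (100000 resamples, two-sided). Genes named in the text are those nearest the 12 IDR peaks of highest signal, the candidates Deaf1, Dfd, Mtk, Drs, Atg8a and Pi3K59F, and up to 3 bound members per list by promoter signal; other names carry a remark. In the gene lists, 8 names were matched through an older symbol held by exactly 1 gene, and 5 names with no unique match (calypso, nos, SmG, lat and Dl) were left out.

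Overlap of replicate lists was counted at 1 bp or more. The alternatives tried were the top 4333 IDR peaks by signal, reciprocal overlap of 50% or summits within 100 bp, promoter windows of 250 and 1000 bp, the most upstream TSS of each gene, flank windows 300 bp to the left or 500 bp to the right, word windows of 100 bp on each side, other backgrounds for genes and peaks, and each replicate left out. Leaving out a replicate meant rebuilding the set from regions in the top 8667 peaks of both other replicates (7465 to 7672 regions). This held for the promoter, word, gene list, divergent promoter and X results. For replicate overlap, IDR peaks in all replicates, rank correlation and named genes, the replicate was only dropped from the comparison. All alternatives for TTCGG, leaving out a replicate for named genes, counting 1 summit per interval, correlating the signals of the nearest replicate summits, and assigning a peak at a divergent promoter only to its nearest gene, were added after seeing the data.

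The procedures were tested on simulated data. For the promoter share of the 8667 IDR peaks, 47.3% was recovered where 46.9% had been set. The TTCG difference was recovered exactly at 4.15 percentage points, which checks the counting alone, since the set value was counted from the same planted windows. Between exchanged flanks, 0 of 2080 6-mers were called. Of 200 random gene lists, 4% passed an unadjusted p of 0.05, and of 200 lists of 30 genes with 18 bound, 100% were called. All of the latter lists give the same test, so this shows only that such a list passes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.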

Results

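Deaf1 is a sequence-specific DNA-binding protein with a SAND domain, which recognises sequences that contain TTCG. It was named for its binding to an autoregulatory region of the Hox gene Deformed (Dfd). Its positions on embryonic chromatin were recorded by ChIP-seq of GFP-tagged Deaf1 in whole embryos, with 3 biological replicates in 1 group. Each replicate list held 30000 peaks with a median signal of 54.4, 52.7 and 41.1 in replicates 1, 2 and 3, and the IDR set held 8667 peaks with a median signal of 533.6. The number of reads behind these lists is unknown. The question the design poses is where in the genome the tagged protein was enriched, near which genes and at which sequences, and whether the replicates gave the same positions.

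The replicates placed their peaks at largely the same sites, and the strongest peaks of all lay at pnt, jing and robo2. On average 84.3% ± 0.686 (SD over the 6 ordered pairs of replicates) of a replicate's peaks overlapped a peak of another replicate. Of the IDR peaks, 8319 (96.0%, 95% exact interval 95.6% to 96.4%) had their summit inside a peak of each of the 3 replicates, and 0 were outside the lists of every replicate. The IDR set was itself derived from rank agreement between the replicates, so a high share follows from its construction. Across IDR peaks, the replicates' signals had Spearman correlations of 0.890, 0.915 and 0.896 (mean 0.900 ± 0.0133, SD over the 3 pairs), taking the highest signal of the replicate interval that holds the summit. With the signal of the nearest replicate summit, an alternative added after the data were seen, the mean was 0.872. Peaks are not independent replicates, so no p is given. Replicates 1 and 3 shared 188 intervals with identical ends, replicates 2 and 3 shared 1 and replicates 1 and 2 shared 0, so no list was a copy of another.

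The highest IDR peak lay at pnt (pointed, an ETS transcription factor downstream of receptor tyrosine kinases; FBgn0003118), on 3R from 23294886 to 23296123, with its summit in an intron 273 bp upstream of an internal TSS. Its signal was 359.8 ± 68.8 times the median of the replicate's list (SD, n = 3). Next came jing (a zinc-finger protein of tracheal and glial development; FBgn0086655), on 2R from 6500660 to 6502709 with the summit 95 bp upstream of the TSS, at 345 ± 64.4 times the list median (SD, n = 3). The peak at robo2 (an axon guidance receptor; FBgn0002543), on 2L from 1419809 to 1421360, lay 41 bp upstream of the TSS and reached 295 ± 43.6 times the median (SD, n = 3). The relative signal fell from pnt to jing to robo2 in each of the 3 replicates, although the gap between pnt and jing was smaller than the SD of either. All 3 peaks were highest in replicate 2 (439, 418 and 344 times the median, against 313.8, 296 and 261 in replicate 3). The other peaks among the 12 highest lay at apt, Eip75B (a nuclear receptor of the ecdysone response), caps, tara, Su(z)2 (a Polycomb group gene), cv-2, pum (a translational repressor), wg (the Wnt ligand Wingless) and hry (the pair-rule gene hairy), from 277 ± 12.996 at apt down to 216 ± 16.7 times the median at hry (SD, n = 3). Of the 12 summits, 11 lay within 273 bp of a TSS. The exception was an intronic peak of tara, on 3R from 16247417 to 16251025, which lay 7480 bp downstream of the nearest TSS. The peaks at pnt, Su(z)2, wg and hry had 0 TTCGG words within 50 bp of their summits, and the peaks at jing, robo2, apt, Eip75B, cv-2 and pum had 2 each.

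**Figure D1:**
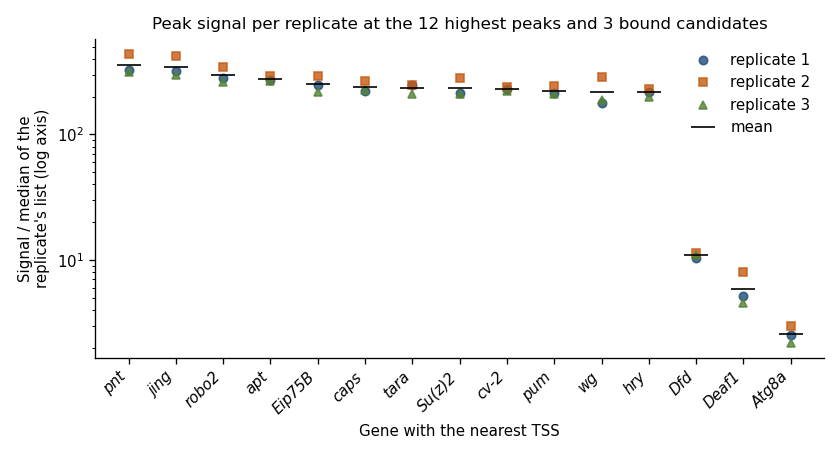
Signal of each replicate divided by the median of its own list of 30000 peaks (log axis) at the 12 IDR peaks of highest signal and at the promoter peaks of Dfd, Deaf1 and Atg8a; symbols are the 3 replicates and bars their mean. The mean runs from 359.8 at pnt to 216 at hry among the highest peaks, against 10.9 at Dfd, 5.89 at Deaf1 and 2.55 at Atg8a.

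Tagged Deaf1 was far more frequent at promoters than random placements were, and sparse in coding sequence. Of the 8667 IDR summits, 4411 (50.9%, 95% exact interval 49.8% to 51.95%) lay within 500 bp of a protein-coding TSS, against 11.5% ± 0.350 (SD) over 1000 random placements, which gave at most 12.5% (one-sided permutation test, p = 0.001, the smallest it can give). With a window of 250 bp the share was 43.6% (6.29% in placements), and with only the most upstream TSS of each gene 37.3% (9.04%). In the top 8667 peaks of each replicate the share was 52.4% ± 0.534 (SD, n = 3). Summits gathered just upstream of the TSS: the median position among promoter summits was -46 bp, and 66.3% (95% exact interval 64.9% to 67.7%) lay upstream. Coding exons held 0.796% of the summits against 14.1% of the placements, and 3′ UTRs held 0.773% against 4.49%. Introns held 30.1% against 39.8%, intergenic sequence 13.9% against 28.0%, and 5′ UTRs outside the promoter windows 0.981% against 0.611% (two-sided permutation p = 0.002 for each of these 5 classes, the smallest the placements can give). The promoter share was 18.5% among the 21333 pooled peaks outside the IDR set (odds ratio 4.58, 95% interval 4.33 to 4.83, Fisher's exact test).

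**Figure D2:**
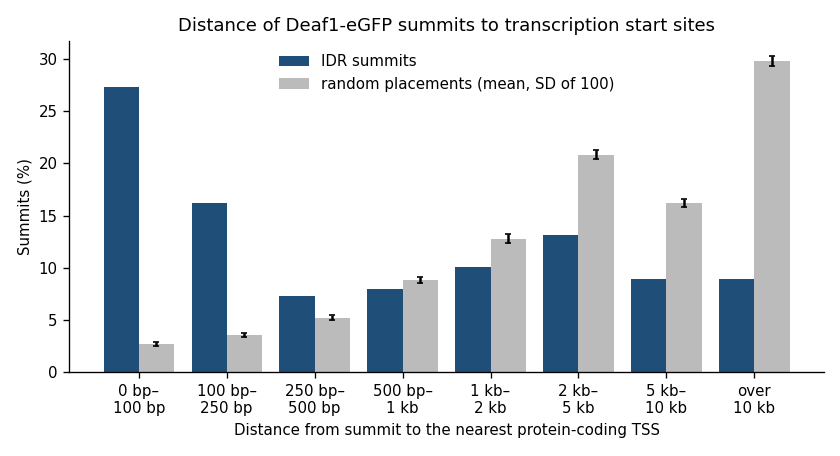
Percent of IDR summits (blue) and of random placements on the same arm (grey, mean with SD of 100 placements) by distance to the nearest protein-coding TSS. Within 100 bp lay 27.3% of the summits against 2.74% of the placements, and over 10 kb away 8.94% against 29.8%.

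Peaks at promoters were also stronger than those over 2000 bp from any TSS. The median IDR signal was 648.9 at 4411 promoter peaks and 440.01 at 2688 peaks over 2000 bp from any TSS, a ratio of 1.47 (permutation test of the difference in medians, p = 1e-05, the smallest that 100000 resamples give). In the replicates' own top lists the ratio was 1.41 ± 0.0510 (SD, n = 3).

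TTCGG, an extension of the Deaf1 core, was enriched at the summits, and the core TTCG itself less so. TTCG stood within 50 bp of 66.3% of the summits against 55.9% of the flank windows, and TTCGG at 28.9% against 16.3%, a ratio of 1.77 (exact McNemar tests, adjusted p = 2.6e-44 and 1.4e-85 over 11 words). In the replicates' own top lists the TTCGG difference was 12.5 ± 0.998 percentage points (SD, n = 3) and the TTCG difference 10.2 ± 1.71. With windows of 100 bp on each side the TTCG difference in the IDR peaks was 4.67 points. Shuffles that keep each dinucleotide count, added after the other results, held TTCG in 57.8% of summit windows and 50.2% of flank windows (means of 20), so most of the TTCG difference was also there after shuffling. Observed over shuffled was 1.15 at summits and 1.11 in flanks for TTCG, and 1.64 and 1.19 for TTCGG. TTCGG was most frequent at the summit itself, at 2.78 times its rate beyond 300 bp. Among the 12 anagrams of TTCG, which share its base composition, TTCG ranked 2 by this difference, after ACGA with 12.7 points. The 2 other anagrams that hold CG averaged 9.66 points and those without CG -0.527, so this rank does not set TTCG apart from other words with CG. Among the 30 anagrams of TTCGG, TTCGG ranked 1, ahead of CGAAC with 10.1 points, which itself holds TTCG on 1 strand. The 11 other anagrams of TTCGG that hold CG averaged 4.32 points and those without CG -0.488. Peaks with more TTCGG words were stronger, with a median signal of 1095 for 2 words and 1557 for 3 or more. The rank correlation of word number and signal across peaks was 0.199 (permutation p = 0.0001, the smallest 10000 permutations give; 0.197 ± 0.0274 in the replicates, SD, n = 3). Peaks are not independent replicates in that test.

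Words of other fly promoter factors differed in how they behaved. The GAGA factor word GAGAG, bound by Trl, was found at 22.1% of the summits and 14.3% of the flanks (exact McNemar test, adjusted p = 8.9e-40). Unlike TTCGG it was commonest not at the summit, with 4.73 occurrences per 1000 positions, but 125 bp to its left, with 5.45, and rose again to 5.12 at 75 bp to the right, against 2.27 beyond 300 bp. The BEAF-32 word CGATA was at 14.3% against 11.1% (adjusted p = 1.0e-09), by the same exact test. The DRE core TATCGAT was at 2.19% against 1.35% (adjusted p = 7.6e-05), the M1BP word GGTCACAC at 0.738% against 0.335% (adjusted p = 0.00067) and the CTCF word AGGTGGCG at 0.450% against 0.208% (adjusted p = 0.012), all by exact McNemar tests. The BEAF-32, DRE and CTCF words hold CG, and shuffles were made for TTCG and TTCGG alone. How much of these differences follows from sequence composition was not tested. The Zelda word CAGGTAG (0.531% in both windows), the E-box CACGTG, the TATA box TATAAA and the Su(Hw) word GCATACTT did not pass the exact McNemar test (adjusted p = 1, 0.20, 1 and 0.87). Of all 2080 6-mers, 400 were more frequent at summits and 464 in flanks at an adjusted p under 0.05. Of the 604 6-mers that hold CG, 318 were enriched, against 82 of the 1476 without CG. Among the 48 with TTCG, 36 were enriched. The 10 with the lowest p were AGCCGA, CCGAAG, GCCGAA, CGAGCG, CGAAGC, CCGAAC, ACGAAG, CGAACG, CCGAGC and CTCGGC; AGCCGA was at 11.8% of summits against 3.66% of flanks, and CCGAAG at 9.12% against 2.49%. Of these 10, 6 contain TTCG on 1 strand.

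**Figure D3:**
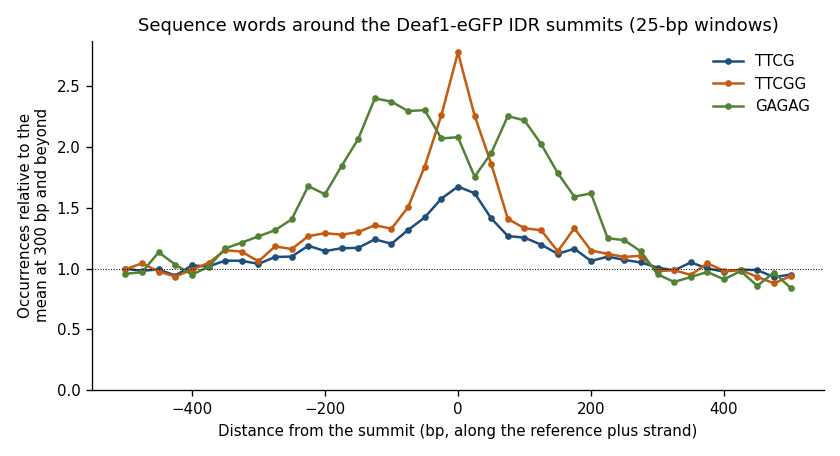
Occurrences of TTCG, TTCGG and GAGAG in 25-bp windows from 500 bp left to 500 bp right of the IDR summits, each divided by its mean at 300 bp and beyond. TTCGG peaks at the summit at 2.78, TTCG at 1.67, and GAGAG lies at 2.08 at the summit, below its values 125 bp to the left and 75 bp to the right.

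The base composition of the summits was spread more widely than that of their surroundings, a feature singled out after its values were seen. Windows of 50 bp on each side with at most 30 G or C bases made up 16.5% of the summits (1431, 95% exact interval 15.7% to 17.3%), but 8.72% and 8.80% of the windows 100 bp to the left and right of the same summits. Farther out the share was as high again, 16.2% at 500 bp to the left and 16.9% at 500 bp to the right. In the replicates' top lists the share was 15.7% ± 2.84 at summits and 8.91% ± 1.31 at 100 bp to the right (SD, n = 3). At these AT-rich summits TTCGG was less frequent than in the flank (4.96% against 16.5%, exact McNemar p = 1.9e-23). At the other 7236 it was at 33.6% against 16.3% (exact McNemar p = 2.0e-127). A window poor in G and C has less room for TTCGG, so the split by composition itself moves these shares. The AT-rich summits had a median signal of 496.3 against 541.7, and 43.0% of them lay at promoters against 52.4%.

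**Figure D4:**
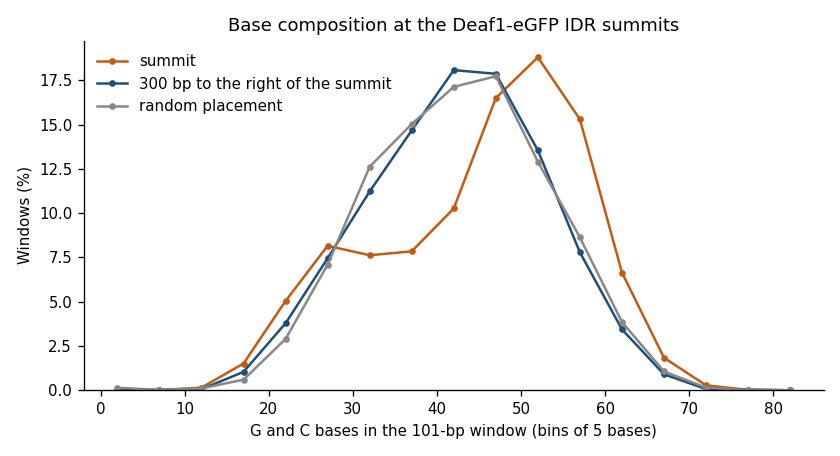
Percent of windows, each 50 bp to both sides of its centre, by number of G and C bases (bins of 5) at IDR summits, 300 bp to their right, and at random placements of the summits on their arms. Summits are fewer than flanks in the bin of 40 to 44 bases (10.3% against 18.1%) and more in the bins of 25 to 29 (8.16% against 7.45%) and 50 to 54 bases (18.8% against 13.5%).

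Segmentation, synaptic and Notch pathway genes were bound far more often than genes in general, and chemosensory receptor, cuticle and antimicrobial peptide genes hardly at all. In total 3878 of 13945 protein-coding genes (27.8%) were bound. Of the 20 lists, 8 had a higher share, 3 a lower share and 9 did not pass the test (Fisher's exact tests, Benjamini-Hochberg adjustment over the lists).

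Segmentation genes, which lay down the embryo's body plan, stood highest, with 24 of 31 bound (77.4%, odds ratio 8.95, 95% interval 3.74 to 24.6, adjusted exact p = 8.8e-08). The share was 80.6% in each replicate's own top list (n = 3). Their strongest promoters were wg at 218 ± 58.2, hry at 216 ± 16.7 and D (Dichaete, a Sox protein) at 54.6 ± 6.10 times the list median (SD, n = 3). Of the synaptic and neuronal genes 18 of 24 were bound (75%, adjusted exact p = 1.0e-05). Among them were nrv3 (a sodium pump subunit of neurons) at 54.4 ± 4.12, scrt (a neural zinc-finger repressor) at 47.1 ± 3.16 and futsch (a microtubule-associated protein of neurons) at 41.7 ± 3.53 times the median (SD, n = 3). Of the 12 genes of the Hox complexes 8 were bound (66.7%, adjusted exact p = 0.013), a share not above the upper limit of 66.7% in gene sets matched on TSS number. The strongest promoters were pb at 16.5 ± 2.49, lab at 15.6 ± 2.13 and Abd-B at 14.2 ± 1.76 times the median (SD, n = 3). The Notch pathway had 16 of 27 members bound (59.3%, adjusted exact p = 0.0025). They were led by the target gene E(spl)m3-HLH at 61.9 ± 0.894, the coactivator mam at 53.4 ± 2.27 and the inhibitor numb at 23.0 ± 1.35 times the median (SD, n = 3).

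Immune signalling and its effector genes parted. Of the Toll and Imd pathway genes 17 of 30 were bound (56.7%, odds ratio 3.41, 95% interval 1.56 to 7.63, adjusted exact p = 0.0025). In the replicates' own top lists the share was 55.6% ± 5.09 (SD, n = 3). Without replicate 2 the list was not called (odds ratio 2.35, adjusted exact p = 0.068), and it was not tested against the peptide genes below. Among the bound pathway genes were the NF-kappaB genes Rel, at 51.9 ± 8.55, and Dif, at 34.1 ± 3.20 times the list median, and the receptor Tl at 11.5 ± 1.99 (SD, n = 3). Another NF-kappaB gene of this list, dl, named here outside the naming rule, was not bound. Of the 30 antimicrobial peptide genes only AttA was bound (3.33%, odds ratio 0.0893, 95% interval 0.00219 to 0.539, adjusted exact p = 0.0038). Its peak had 2.14 ± 0.185 times the median (SD, n = 3) and lay 443 bp upstream of the TSS.

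Muscle structure genes were bound at 13 of 26 (50%, adjusted exact p = 0.031). The strongest were Msp300 at 61.0 ± 5.27, Zasp52 at 52.9 ± 4.29 and Prm (paramyosin) at 50.4 ± 4.19 times the median (SD, n = 3). Polycomb and Trithorax group genes, which keep developmental genes silent or active, were bound at 14 of 29 (48.3%, adjusted exact p = 0.038). The strongest were the neighbours Su(z)2 at 236 ± 39.7 and Psc at 69.1 ± 10.4, and corto at 34.1 ± 5.04 times the median (SD, n = 3). Cytoplasmic ribosomal protein genes were bound at 44 of 91 (48.4%, odds ratio 2.45, 95% interval 1.58 to 3.78, adjusted exact p = 0.00012). The share was 47.6% ± 4.96 in the replicates' own top lists (SD, n = 3). Signals were lower here. RpS28a had 9.34 ± 0.175 times the median (SD, n = 3), and RpL41 and RpL34b, each inside a peak of 2 replicates, had 10.3 ± 0.569 and 6.72 ± 0.377 (SD, n = 2). The summit counted for RpS28a lay 483 bp downstream of its TSS, past the end of this short gene and in a 5′ UTR of another annotated gene. Counting the strongest promoter summit of each bound gene, TTCGG was at 13.6% of the 44 summits of ribosomal protein genes and at 33.0% of the 3218 summits of the other genes alone; 20 of the 44 also lay at the TSS of another bound gene. Genes with more annotated TSSs were bound more often, from 19.7% with 1 TSS to 82.6% with 5 or more, and 3 of the 8 higher shares did not exceed the central 95% of random gene sets matched on that number. These were the muscle genes (45.1% on average in matched sets, upper limit 61.5%), the Polycomb and Trithorax genes (33.7%, upper limit 48.3%) and the Hox genes (37.5%, upper limit 66.7%).

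The lowest share was that of the chemosensory receptors, the odorant, gustatory and ionotropic receptor families, with 1 of 180 bound (0.556%, odds ratio 0.0142, adjusted exact p = 4.7e-23). The bound gene was Or67a, at 2.09 ± 0.258 times the median (SD, n = 3). Cuticle protein genes followed with 6 of 117 (5.13%, odds ratio 0.139, adjusted exact p = 5.2e-09). The strongest were Cpr57A at 12.9 ± 0.740, Cpr62Bc at 8.88 ± 0.599 and Cpr73D at 8.84 ± 1.22 times the median (SD, n = 3).

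The other 9 lists did not pass the test (adjusted p from 0.31 to 1). Mitochondrial ribosomal proteins had 24 of 73 bound (32.9%, above the upper limit of 31.5% in gene sets matched on TSS number, permutation p = 0.017), although giving each peak only to its nearest gene turned them to a lower share (odds ratio 0.457, adjusted exact p = 0.043). Their strongest promoters were mRpS10 at 25.4 ± 6.49, mRpS23 at 19.7 ± 2.78 and mRpL41 at 18.6 ± 4.68 times the median (SD, n = 3). Oxidative phosphorylation had 16 of 77 (20.8%), with ND-ASHI and Cyt-c-p highest, and the proteasome 9 of 48 (18.8%), with Rpn3, Rpn13 and Rpn6 highest. Translation factors had 14 of 53 (26.4%), with eIF4EHP at 24.0 ± 4.34 and eEF1alpha2 at 23.1 ± 0.807, and aminoacyl-tRNA synthetases 7 of 33 (21.2%), with SerRS at 9.49 ± 3.13 (SD, n = 3). Splicing genes had 11 of 32 (34.4%), among them SmD3 and U2af50; insulator and architectural proteins had 5 of 20 (25%), among them Chro at 21.7 ± 5.17 and Cp190 at 14.5 ± 3.95 (SD, n = 3). Autophagy genes had 8 of 25 (32.0%), led by Vps15 and Atg17, and cell cycle and replication genes 9 of 39 (23.1%), where the mitotic phosphatase stg stood out at 31.4 ± 1.00 and CycE followed at 5.48 ± 0.487 times the median (SD, n = 3).

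Against a narrower background each of the 8 calls of a higher share was lost, as were those of a lower share. Among the 5526 genes with a relaxed pooled summit within 500 bp of a TSS, 0 of 20 lists passed (Fisher's exact tests; lowest adjusted p = 0.0543, for segmentation and cuticle protein genes; 1 list higher and 3 lower at an unadjusted p under 0.05). That background keeps every bound gene and drops only unbound ones, so lists shrink (chemosensory receptors to 6 genes, cuticle proteins to 17) and 70.2% of its genes outside the chemosensory list are bound. Part of the loss follows from this construction. Only 1 antimicrobial peptide gene is left there, so its list could not pass. The odds ratio there was 10.3 for segmentation, 3.84 for synaptic, 3.40 for Hox, 2.41 for Toll and Imd, 1.99 for Polycomb and Trithorax and 1.38 for muscle genes. It was 1.13 for the Notch pathway, 1.04 for cytoplasmic ribosomal proteins, 0.231 for cuticle proteins and 0.0848 for chemosensory receptors. Without replicate 2, 5 of the 8 lists were called higher, and the Toll and Imd, Polycomb and Trithorax, and muscle lists were not (adjusted exact p = 0.068, 0.20 and 0.13). Without replicate 1 the Polycomb and Trithorax and the muscle lists were lost (adjusted exact p = 0.093 and 0.11). In the stronger 4333 peaks the Hox and cytoplasmic ribosomal protein lists were lost (adjusted exact p = 0.082 and 0.20), while proteasome and oxidative phosphorylation genes passed with a lower share (odds ratios 0.197 and 0.383, adjusted exact p = 0.022 and 0.031). The Hox list was also lost with only the most upstream TSS of each gene (adjusted exact p = 0.31), and the Polycomb and Trithorax list with a window of 250 bp (adjusted exact p = 0.091).

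**Figure D5:**
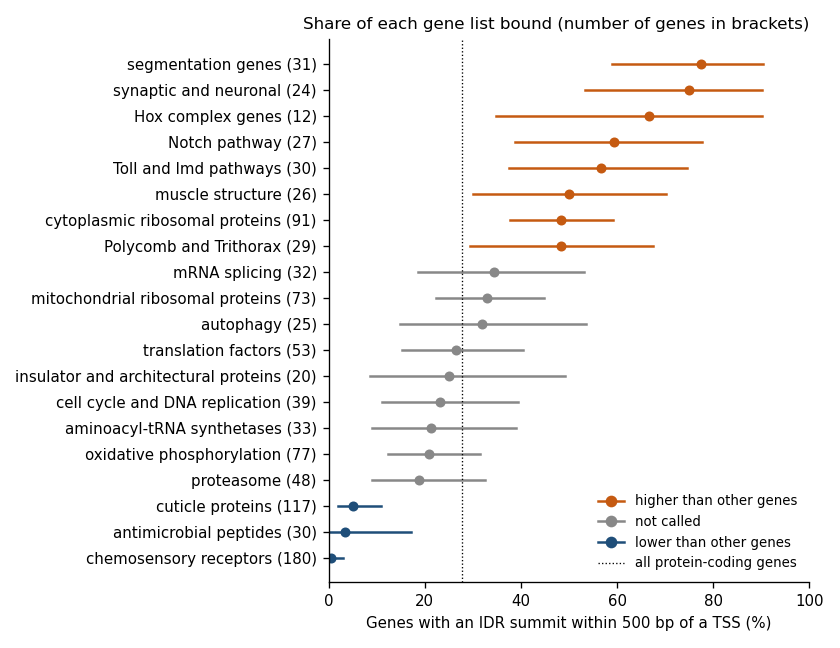
Percent of each list's genes with an IDR summit within 500 bp of a TSS (points, with 95% exact intervals; number of genes in brackets), coloured by the Fisher's exact test after adjustment; the dotted line marks all protein-coding genes at 27.8%. Segmentation genes (77.4%) and synaptic genes (75%) lie far right of the line, chemosensory receptors (0.556%) far left.

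Of the candidate genes, 3 had an IDR peak at a promoter. At Dfd (FBgn0000439) the peak on 3R from 6791418 to 6792005 had its summit at 6791704, 132 bp upstream of the TSS, at 10.9 ± 0.480 times the list median (SD, n = 3) and rank 1420 of 8667. At Deaf1 itself (FBgn0013799) the promoter peak on 3L from 19817753 to 19818202 lay 171 bp upstream of the TSS at 5.89 ± 1.80 times the median (SD, n = 3). A stronger peak lay 2475 bp upstream, from 19815444 to 19816110, with an IDR signal of 1628.5 against 889.95 at the promoter. The summit of this stronger peak lay in an intron of another annotated gene, and a further summit of the interval, 2274 bp upstream, in a 5′ UTR. At Atg8a, a ubiquitin-like protein of autophagosomes (FBgn0052672), the summit on X at 10767417 lay in an intron 111 bp upstream of an internal TSS, at 2.55 ± 0.390 times the median (SD, n = 3). Pi3K59F, the lipid kinase of autophagosome formation (FBgn0015277, 2R), had at its promoter only a relaxed peak 122 bp upstream of its start, with a pooled signal of 120.4, a rank of 15707, and a replicate peak in replicates 1 and 2 alone. The antimicrobial peptide genes Mtk (FBgn0014865, on 2R from 15408846 to 15409113) and Drs (FBgn0283461, on 3L from 3369556 to 3369942), both reported to be controlled by Deaf1 in the adult immune response, had no summit within 500 bp in any of the 5 lists and no pooled summit within 5000 bp of the gene.

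Genes of divergent promoters were bound more often when a shared summit counted for both genes of a pair, but not under other counts. Of 3686 genes with an opposite-strand TSS within 500 bp upstream, 32.5% were bound, against 26.1% of 10259 others (odds ratio 1.36, 95% interval 1.25 to 1.48, Fisher's exact test, p = 3.0e-13). Giving each peak only to its nearest gene turned the direction (19.4% against 24.9%, odds ratio 0.727, exact p = 8.7e-12), and in the stronger 4333 peaks the odds ratio was 0.975 (exact p = 0.64). A summit shared by a pair counts for both genes in the first count and for 1 in the nearest-gene count. The first rule itself raises the share of divergent genes and the nearest-gene rule lowers it. Neither count therefore decides whether divergent promoters were bound more often. Genes of a pair are not independent, which these p-values ignore.

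The X and the large autosome arms differed little, and chromosome 4 was sparsely bound. Of the X-linked genes 663 of 2196 (30.2%) were bound, against 27.5% of the genes of 2L, 2R, 3L and 3R (odds ratio 1.14, 95% interval 1.03 to 1.26, Fisher's exact test, p = 0.010). The call was lost in the stronger peaks (odds ratio 0.989), without replicate 1 (1.06, exact p = 0.27), without replicate 2 (1.07, exact p = 0.20), with a promoter window of 250 bp and with 1 TSS per gene. On chromosome 4, 8 of 80 genes were bound (10%, 95% exact interval 4.42% to 18.8%), against 27.9% elsewhere (odds ratio 0.287, 95% interval 0.119 to 0.597, Fisher's exact test, p = 0.00014); this comparison was added after the values were seen.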

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

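The tests of TTCGG at peaks away from promoters, of ribosomal protein summits against other bound summits, of all 20 lists against matched gene sets, and of TTCGG outside the IDR set were chosen after results were seen. The Deaf1 word also appeared outside the set that the comparisons rest on. Among the 21333 relaxed pooled peaks that did not enter the IDR set, TTCGG stood at 20.4% of the summits and 15.9% of their flanks (exact McNemar p = 1.2e-33), a difference of 4.52 points beside 12.6 points at the IDR peaks; these 2 differences were not tested against each other. It was singled out because it is a signal in peaks left out of the comparisons. These peaks include weaker summits inside intervals of the IDR set, as at Dfd, 91 bp downstream of its start. How much of the difference comes from such summits was not tested. No control immunoprecipitation was used here to set a background.

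The enrichment of TTCGG at summits was weighed against sequence composition: in shuffles of the summit windows that keep each dinucleotide count, 17.6% held TTCGG on average and at most 18.2% over 20 shuffles, against 28.9% observed (observed over shuffled 1.64 at summits and 1.19 in flanks), which argues against dinucleotide content as the whole cause. Only 152 peaks had summit and flank windows with equal CpG number and similar G plus C, and their difference was 2.63 points (95% bootstrap interval -5.92 to 11.2, below the 12.6 points of all peaks; exact McNemar p = 0.627), the outcome named in advance for base composition as the cause. TTCGG itself holds a CpG, so equal CpG numbers partly fix the word, and a part played by base composition stays open. Promoter sequence of protein-coding genes is argued against as the whole cause by the 4256 peaks over 500 bp from any protein-coding TSS. There the difference was 11.6 points. Promoters of non-coding genes were not taken out of these peaks, so a part played by them stays open. Direct recognition by Deaf1 was not tested, since the design holds no sample for it. The rise of signal with word number held in 4 of 5 equal groups of windows by G plus C content (permutation p under 0.05, rank correlations from 0.125 to 0.243), while the group poorest in G and C had 0.0451 (permutation p = 0.059).

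The high bound share of the 8 lists was weighed against gene structure and against promoters at which any peak is called. The 8 lists were picked for a high bound share, so their pooled share (57.1% of 268 genes, against 35.4% in random gene sets matched on TSS number) and their pooled odds ratio among genes with a relaxed pooled summit at a TSS (1.74) decide nothing. Of all 20 lists, 6 exceeded the central 95% of 10000 matched sets, where chance gives 0.5 (exact binomial p = 7.0e-06), which argues against TSS number as the whole cause. The binomial test takes the lists as independent. Some lists share members, and neighbouring members can share a peak, so this p can be too small. Of the 6 lists, 5 are among the 8. The other, mitochondrial ribosomal proteins, turned to an odds ratio of 0.457 with each peak given to its nearest gene (adjusted exact p = 0.043). For muscle, Polycomb and Trithorax and Hox genes TSS number stays open. Promoters where any peak is called stay open too: 0 lists were called in that background (Fisher's exact tests; 1 higher at an unadjusted p under 0.05), but it drops only unbound genes, so the loss partly follows from its construction, and odds ratios ran from 1.04 for cytoplasmic ribosomal proteins and 1.13 for the Notch pathway to 10.3 for segmentation genes. How accessible these promoters are in embryos, and any biological preference of Deaf1, were not tested, since the design has 1 group.

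Ribosomal protein genes had TTCGG at a smaller share of their bound summits than the other bound genes. Their share of 48.4% exceeded that of matched random sets (34.7% on average, upper limit 44.0%), which argues against TSS number as the whole cause. Counting the strongest promoter summit of each bound gene, TTCGG was at 13.6% of their 44 summits, -11.4 points relative to their own flanks (exact McNemar p = 0.302), and at 33.0% of the 3218 summits of the other genes alone (odds ratio 0.321, 95% interval 0.110 to 0.768, Fisher's exact test, p = 0.0055); 20 of the 44 are shared with another bound gene and were counted here only. Only TTCGG was counted at these summits, not the core TTCG, and most of the other summits lack TTCGG too. The median signal was 533.6 at the bound ribosomal protein genes and 648.9 at all promoter peaks. TTCGG number rises with signal and the groups were not matched on it, so a part played by peak strength stays open. Recovery of these promoters without the Deaf1 sequence, through another protein or through background of strongly transcribed genes, is thus only a candidate explanation. Which of these applies, if any, was not tested.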

How the results depend on the processing

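All alternatives for TTCGG, leaving out a replicate for named genes, counting 1 summit per interval, taking the signal of the nearest replicate summit and giving peaks at divergent promoters to the nearest gene only were chosen after the data were seen. No paired analysis was possible because the series holds 1 group. The promoter share, the promoter to distal signal ratio, the TTCG difference and the number of enriched 6-mers kept their direction and their side of the threshold, or stayed within 1.5 times, under each alternative run, although the TTCG difference fell to 4.67 points with windows of 100 bp on each side. Replicate overlap was 73.3% at reciprocal overlap of 50%, 63.9% for summits within 100 bp, 87.8% in the top 8667 peaks, and 84.1% to 84.5% with a replicate left out. The share of IDR peaks in all replicates was 92.4% for summits within 100 bp, 75.9% in the top lists, and 97.1% to 97.496% with a replicate left out, where only 2 lists must hold the peak. The rank correlation was 0.928 in the stronger 4333 peaks, 0.849 over the pooled relaxed peaks, 0.872 at the nearest replicate summit, and 0.890 to 0.915 with a replicate left out. That last range is the single pairs of replicates already given, so it is no separate check. The number of lists called higher was 5 to 8 with a replicate left out (5 without replicate 2) and 0 among genes with a relaxed pooled peak (Fisher's exact tests; 1 at an unadjusted p under 0.05). The divergent promoter odds ratio turned to 0.975 in the stronger peaks and 0.727 for the nearest gene, where a shared peak counts for 1 gene only. The X odds ratio was 0.989 in the stronger peaks, 1.06 to 1.11 with a replicate left out, 1.10 with a 250 bp window and 1.08 with the most upstream TSS. Of 199 alternatives for single lists, 164 kept the call, 19 lost it, 2 gained it (proteasome at 0.197 and oxidative phosphorylation at 0.383, both lower, in the stronger peaks) and 14 changed direction, of which 1 also gained a call. Those that changed direction were not called before: splicing to 0.843 (stronger peaks) and 0.752 (nearest gene); autophagy to 0.395 (stronger peaks), 0.411 to 0.955 (a replicate left out) and 0.679 (relaxed background); insulator proteins to 1.01 to 1.02 (a replicate left out) and 1.02 (250 bp); mitochondrial ribosomal proteins to 0.924 (250 bp) and 0.457 (nearest gene, a lower share past the threshold at adjusted exact p = 0.043); translation factors to 1.10 without replicate 2 (0.980 to 1.10 with a replicate left out). The cause of these changes was not tested, and leaving out a replicate for a list also meant rebuilding the peak set. With replicate 2 left out, wg (184 times the list median) fell below hry (208). The TTCGG difference kept its side of the threshold in 9, from 11.6 to 18.5 points. Among genes with a relaxed pooled peak the antimicrobial peptide list, with 1 gene left, gave no odds ratio. Sequencing depth is unknown, so its effect on peaks near the ends of the lists is open.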

Other observations

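All tests in this part were chosen after the peak positions were seen. Counting each gene with 2000 bp on each side, Eip75B on 3L held 39 IDR summits, tara on 3R 34 and Tlk on X 28, followed by hth, mam, ush and jing with 22 each; tara had the highest density of the 10 genes with most summits, 8.79 per 10 kb. Of the gaps between neighbouring summits, 19.2% were at most 1000 bp, against 6.31% on average and 7.18% at most over 1000 random placements (permutation p = 0.001, the smallest it can give). With 1 summit per interval the share was 8.67%, against 5.60% on average and 6.59% at most after placement (permutation p = 0.001). The placements ignore the gathering of summits at promoters, which can itself give short gaps, so these tests do not show any clustering beyond it.

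Summits lay near tRNA, snRNA and ncRNA genes more often than random placements did. Of 211 tRNA genes over 1 kb from a protein-coding TSS, 26 (12.3%) had an IDR summit within 500 bp of their start, against 5.93% after random placement (permutation p = 0.001, the smallest it can give), and of 27 such snRNA genes 5 (18.5%) did (permutation p = 0.02). Of 184 such snoRNA genes 9 (4.89%) did, with 5.87% after placement (permutation p = 0.78). Of 2325 such ncRNA genes 216 (9.29%) did, against 5.80% (permutation p = 0.001). tRNA genes lie in clusters, so neighbouring genes can share a peak and these p-values are too small.

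Pairs of TTCG at most 40 bp apart were 3.35 times as frequent in the 201 bp around summits as in flanks 500 bp away when both copies faced the same way (95% bootstrap interval over peaks 3.12 to 3.62) and 2.29 times when they faced each other or apart (2.13 to 2.47). Pairs also become more frequent where single copies do, and this was not taken out of these ratios. For same-facing copies the ratio was 4.10 at start-to-start distances that are multiples of 5 bp and 3.14 at other distances. The highest single ratio, 4.56, was at 10 bp, but the classes overlapped. Distances of 12 and 24 bp had 4.29 and 4.36, above 3.61 at 25 bp and 3.22 at 40 bp, so no spacing rule follows. In windows with exactly 2 copies, 55.2% faced the same way at summits and 53.9% in flanks (odds ratio 1.05, 95% interval 0.924 to 1.20, Fisher's exact test, p = 0.43), so the excess of same-facing pairs was not detected there.

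Of the AT-rich summits 96.1% ± 2.34 had a replicate summit within 100 bp, against 97.4% ± 0.366 of the other summits (SD, n = 3), in a set already selected for agreement between replicates. The 6-mer that most separated them from the sequence 100 bp to the right was TTAAAA, at 50.5% against 24.2% (exact McNemar test, adjusted p = 3.2e-46). These summits were selected for few G and C bases and the windows beside them were not, so an excess of A/T words follows from the selection.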
